A study of Homo sapiens with 16 samples.

How the data were processed

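The measurement was mRNA sequencing of 8 human blood cancer cell lines, each kept with 1 of 2 peptides, which gave 16 libraries. Per the labels, one peptide (3R) does not bind DPY30 and served as the control, and the other (Y518R) binds DPY30. Per the labels' protocols, the culture medium was Advanced RPMI, the serum (fetal bovine) was at 2.5%, RNA was extracted with a Direct-zol kit, polyadenylated RNA was selected, and libraries were made with a NEBNext Ultra RNA kit at a sequencing service. The peptide dose and the time on peptide are not given in the sources used here.

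The deposited values are counts: whole numbers of reads per gene, not normalized, for 23230 gene symbols in each library. The submitters' processing notes name CASAVA 1.8.4, TopHat2 2.1.1, HTSeq 0.6.1, DESeq2 3.0 and DESeq, with no step given for each. The same notes name the genome builds GRCh38 and hg19 without saying which was used for these counts, so no coordinates are printed. The strand setting of the counting is not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies therefore cannot be told apart with certainty, and values of histone, globin, HLA, metallothionein, ribosomal protein, KRAB zinc finger and pseudogene symbols are uncertain for that reason. Each library also had 5 entries that name no gene, which were kept out of library sizes and tests. Reads given to no gene made up 17.7% to 26.9% of the reads given to a gene, to no gene or to several genes in 15 libraries and 44.7% in the RAJI 3R library; reads shared by several genes made up 1.37% to 2.18%.

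Libraries held 19354300 to 43003124 gene counts. A count of 0 allows up to 3 counts, which is 0.0698 to 0.155 CPM (counts scaled to a common library size) depending on the library. Counting intervals are exact 95% intervals for the ratio of 2 counts. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

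The groups were the 2 peptides, and the pairs were the 8 cell lines, both taken from the labels. The pairing was checked once: all 16 libraries had the other library of the same line as their best match, with a Spearman correlation of 0.969 to 0.981 within lines and at most 0.925 between lines, and deviations from the peptide means correlated at 0.945 to 0.972 within lines. No line's pair was the same library deposited again: chi-square per degree of freedom between the libraries of a line was 8.66 to 65.5. Nothing in the labels says that libraries came from separate cultures beyond the different lines, so p-values measure the spread between these lines under 1 library per peptide each, part of which may be technical.

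Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling, the filterByExpr filter at a minimum count of 10 (13043 genes kept), cell line as the block, and Benjamini-Hochberg adjustment with calls at an adjusted p under 0.05. All libraries were fitted together for 4 comparisons of Y518R with 3R: all 8 lines, the 4 lines with an MLL fusion, the 4 other lines, and the difference between these classes. The comparison over all 8 lines had its own fit with a single peptide term. The other comparisons shared a fit with a peptide term for each class. The SE given with an edgeR change is the absolute log2 change divided by the square root of the quasi-likelihood F. It is rough for genes with few counts. Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 where at least 5 members were tested, and again with camera at an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Of 27 lists with 580 entries, 25 could be tested; 11 entries, all of a list of mitochondrially encoded transcripts, were not analysed here. For 8 genes (DPY30, ASH2L, MYC, HOXA9, MEIS1, BCL2, CDKN1A and MKI67) the mean log2 ratio over the 8 lines was tested by an exact 2-sided sign-flip permutation test, whose smallest possible p is 0.00781. Likeness of the lines' responses was measured by the mean pairwise Pearson correlation of log2 ratios over tested genes, with an exact 2-sided sign-flip test over lines.

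Within a single line there was 1 library per peptide, so no test was made and single lines are described without p-values. Log2 ratios there are of TMM-scaled CPM with a prior count of 2. Genes were counted as at least 2-fold different among those at a CPM of 10 or more in either library. The median of each list, over members at a CPM of 1 or more, was placed among the medians of 10000 random lists of the same size matched on mean expression. Members of random lists were drawn independently, so this place ignores that genes of a list move together and is not a test. CPM of single genes are TMM-scaled. A summed CPM was taken over histone genes and RNA genes taken, by their symbols, to lack poly(A) tails. The floors in CPM and this sum are of the library total without TMM scaling, and bounds of the kind "at least N-fold" set 3 counts in the place of 0 at TMM-scaled library sizes.

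The comparisons, gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. The rule named, over 8 lines, the 10 genes of each direction with the largest change among those passing, or, with fewer than 3 passing, the 5 of each direction with the lowest p, said not to pass. For each class of lines it named the 5 of each direction, or the 3 with the lowest p where fewer than 3 passed, at the same direction in all 4 lines for those passing. It named the 5 of each direction with the lowest p for the difference, 3 members of each called list, at most 2 of other lists, the 2 highest and 2 lowest log2 ratios of each line among genes with at least 200 counts over both libraries, and always the 8 genes listed above. A few genes that the rule picked are left out of the text. Exceptions, chosen after their values were seen, are the genes called only by another tool or setting, members singled out by adjustment over a list alone, list members and marker genes given for single lines, and the genes at least 2-fold different in KOPN8 and K562.

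The test was checked on counts simulated from the real genes' means, library sizes and fitted dispersion for 13043 genes, with 50 genes changed at each fold. It recovered, at 1.5-, 2-, 3- and 4-fold, 76%, 90%, 98% and 100% of changed genes over all 8 lines; 66%, 80%, 96% and 100% in the MLL-fusion lines; 60%, 82%, 98% and 100% in the other lines; and 24%, 70%, 90% and 96% for the difference, where the change was put in the MLL-fusion lines alone. Unchanged genes called in these simulations numbered 11, 9, 22 and 11. With no change simulated over 8 lines it called 0 genes and 1 list. Within the lines given a change, the simulated fold was the same in each line.

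Alternatives were RLE and upper quartile scaling, no filter, a minimum count of 50, at least 10 counts in 2 or more libraries, DESeq2 1.42.0, limma-voom, robust estimation, no replicate block, an adjusted p of 0.10, a separate fit of each class, a correction for GC content and gene length with the block kept (12470 tested genes, 95.6%, had both values), and leaving out each cell line in turn. Leaving out RAJI and THP1 together, leaving out histone genes and RNA genes without poly(A) tails, and an exact sign-flip test of list means over lines were chosen after seeing the data.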

Results

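RNA was sequenced from 8 established blood cancer lines exposed to a peptide that binds DPY30 (Y518R) or to one that does not (3R). DPY30 is a shared subunit of the SET1/MLL complexes, which methylate lysine 4 of histone H3, and the series concerns peptides meant to inhibit DPY30 activity and the growth of blood cancer cells. Per the labels, 4 lines carry a fusion of the MLL gene: MOLM13 and THP1 with MLL-AF9, RS4-11 with MLL-AF4 and KOPN8 with MLL-ENL. The 4 other lines were K562 with BCR-ABL, RAJI from Burkitt's lymphoma, JURKAT, a T cell leukemia line, and P493-6, a model of Burkitt's lymphoma. Each line had 1 library per peptide, so the replicates of a comparison were cell lines (n = 8, or 4 per class). Depth ran from 19354300 gene counts in RAJI 3R to 43003124 in RS4-11 3R.

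Markers matched the named lines in both libraries. HOXA9, a homeobox gene turned on by MLL fusions, was at 19.2 CPM with 3R and 27.1 with Y518R in MOLM13, 13.0 and 10.2 in THP1, 20.3 and 19.4 in RS4-11 and 49.4 and 48.2 in KOPN8, against 0 or 1 count in each library of the 4 other lines. The myeloid gene LYZ was at 546 and 590 CPM in MOLM13 and at 758 and 529 in THP1. The B cell gene CD79A was at 430 and 460 CPM in RS4-11, 508 and 558 in KOPN8, 552 and 554 in RAJI and 403 and 432 in P493-6. CD3D, a part of the T cell receptor complex, was at 387 and 371 CPM in JURKAT, and the erythroid regulator GATA1 at 279 and 329 CPM in K562. Of the 15 T cell markers, all 15 were at 10 CPM or more in JURKAT 3R, and only 3 passed the expression filter over all libraries, so that this list could not be tested. MYC was at 5280 and 4630 CPM in P493-6.

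The first question was whether the target, its partner and genes tied to MLL-fusion leukemia and growth differed between peptides. DPY30 mRNA was at 27.4 to 53.6 CPM with 3R and 25.8 to 47.6 CPM with Y518R, and its mean log2 ratio was −0.060 ± 0.16 (SD, n = 8 lines; 4 of 8 higher; exact p = 0.359). The 95% interval of that mean was 0.13 to either side. ASH2L, the subunit that DPY30 contacts, had a mean of 0.031 ± 0.21 (5 of 8 higher; exact p = 0.672, n = 8). MYC had a mean of 0.032 ± 0.45 (exact p = 0.758, n = 8) that joined opposite values in the MLL-AF9 lines, 0.94 in MOLM13 (9016 to 15327 counts) and −0.69 in THP1 (6222 to 3701 counts). HOXA9 in the 4 lines with measurable counts had log2 ratios of 0.50 in MOLM13, −0.35 in THP1, −0.069 in RS4-11 and −0.035 in KOPN8 (mean over 8 lines −0.12 ± 0.34, exact p = 0.344). That mean takes in the other lines, at 0 or 1 HOXA9 count in each library, and the edgeR fit gave −0.0054. MEIS1, a HOXA9 cofactor, had a mean of −0.25 ± 0.82 (1 of 8 higher; exact p = 0.484, n = 8). Its higher value in THP1 rested on 2 and 6 counts, and without THP1 the mean was −0.43, past an unadjusted exact p of 0.05. That mean drew mostly on RAJI (52 to 13 counts) and JURKAT (9 to 3 counts), and P493-6 had 0 counts. In the lines with the most MEIS1 the fall was small, from 54.0 to 50.1 CPM in MOLM13, 118 to 112 in RS4-11 and 190 to 177 in KOPN8. The anti-apoptotic gene BCL2 had a mean of 0.035 ± 0.66 (exact p = 0.742, n = 8), against −0.071 in the edgeR fit, which weights lines by their counts. The cell cycle inhibitor CDKN1A had 0.045 ± 0.34 (exact p = 0.719, n = 8) and the proliferation marker MKI67 0.061 ± 0.29 (exact p = 0.562, n = 8). Adjusted over these 8 genes the p was 0.758 for each, and no difference exceeded the spread between lines.

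**Figure D1:**
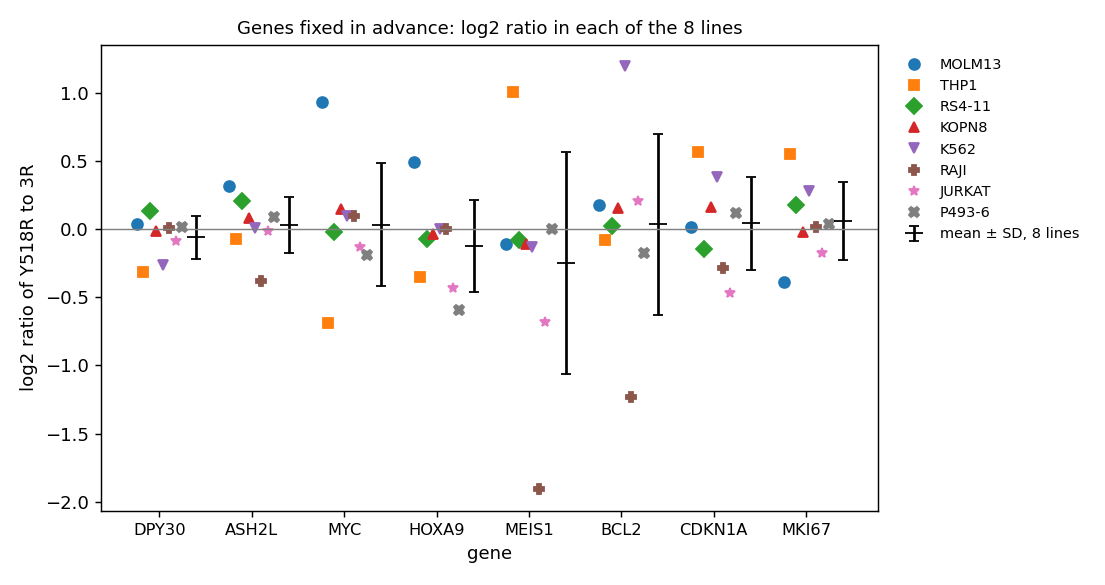
Log2 ratio of Y518R to 3R (y axis) for the 8 genes fixed in advance (x axis), with 1 point per cell line and the mean and SD over 8 lines. DPY30 ratios lie between −0.32 and 0.13, while MYC ratios run from −0.69 in THP1 to 0.94 in MOLM13.

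Over all 8 lines the comparison asked for genes that respond to the DPY30-binding peptide whatever the line. Genes of DNA replication and S phase were slightly higher with Y518R, with all 26 tested members above 0 and a median log2 change of 0.099, and so were MYC targets of ribosome biogenesis and metabolism, with all 30 members above 0 and a median of 0.092. Replication-dependent histones, whose mRNAs typically lack poly(A) tails, were lower, with 0 of 13 members above 0 and a median of −0.26. Whether each listed histone mRNA lacks a tail was not tested. No single gene passed. These 3 lists were called by camera at its preset correlation (adjusted p = 6.96e-11 for S phase, 1.98e-09 for MYC targets and 0.00489 for histones), with adjusted p = 0.602, 0.712 and 0.989 with an estimated correlation. Fry called 0 lists (lowest adjusted p 0.411), and the exact sign-flip test over lines, added after seeing the data, called 0 (S phase p = 0.0547, adjusted 0.684, list mean higher in 6 of 8 lines; MYC targets p = 0.141, adjusted 1, 6 of 8). The histone call rested on RAJI, whose 3R library stood apart in reads given to no gene (44.7%): without RAJI its adjusted p was 0.958. Without RAJI and THP1 together, 5 lists were called.

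In the S phase list, the helicase subunit MCM7 had a log2 change of 0.17 ± 0.069 (SE; 7 of 8 lines higher), the GINS complex gene GINS1 0.16 ± 0.064 (7 of 8) and the flap endonuclease FEN1 0.13 ± 0.055 (6 of 8). In the MYC target list, the ribosome assembly factor MRTO4 had 0.20 ± 0.068 (8 of 8), UTP20 0.15 ± 0.057 (7 of 8) and ODC1, the first enzyme of polyamine synthesis, 0.26 ± 0.11 (6 of 8). Among histones, HIST1H1E had −0.86 ± 0.56, HIST1H2BD −0.26 ± 0.18 and HIST1H4C −0.30 ± 0.22, with the lowest ratios in RAJI (−5.88, −1.51 and −1.89). None of these members passed by itself, and 0 members of any list passed over all genes or adjusted over the list alone.

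The 22 other lists were not called, at adjusted p from 0.0527 to 0.98 (camera, preset correlation). MLL fusion target genes had a median of −0.057 with 5 of 23 members above 0, and the SET1/MLL complex with other DPY30 partners 0.0089 with 11 of 19. Stress and metabolic lists had medians near 0: p53 targets 0.011, the BCL2 family −0.073, cholesterol synthesis 0.0097, the ATF4 and amino acid response −0.044, endoplasmic reticulum chaperones 0.0053, the heat shock response 0.048, NRF2 targets −0.0050, metallothioneins −0.051, lysosomal genes −0.011, hypoxia and glycolysis genes −0.066 and oxidative phosphorylation −0.0061. Of the BCL2 family 2 of 12 members lay above 0. Its exact sign-flip test over lines gave p = 0.0547 (adjusted 0.684), the same as for S phase, with the list mean higher in 2 of 8 lines. The G2/M list was at 0.032, cytosolic ribosomal proteins at −0.043, NF-kappaB targets at −0.023, the interferon response at 0.068 and immediate early genes at −0.049. Lineage lists were at −0.096 for MHC class II, 0.014 for myeloid, −0.0086 for B cell and −0.077 for erythroid and megakaryocyte markers. For the cholesterol, lysosome, myeloid and B cell lists the mean had the opposite sign to the median and the test took the mean's side; for p53 targets the test pointed down while both were above 0.

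The genes with the lowest p did not pass (edgeR adjusted p = 1 for each). Higher with Y518R were SPRYD3 at 0.25 ± 0.069 (SE; 8 of 8 lines), the amino acid transporter SLC43A2 at 0.46 ± 0.14 (7 of 8), the cortical actin protein cortactin CTTN at 0.39 ± 0.12 (8 of 8), the actin-oxidizing enzyme MICAL2 at 0.50 ± 0.16 (7 of 8) and the carboxylesterase CES2 at 0.17 ± 0.055 (8 of 8). CTTN stood apart in THP1, at 1.60 against at most 0.45 elsewhere. Lower were YPEL2 at −0.34 ± 0.091 (0 of 8 higher), KLHL24 at −0.30 ± 0.083 (1 of 8 higher) and the zinc finger gene ZNF714 at −0.31 ± 0.088 (1 of 8 higher). C1QL4 had −1.17 ± 0.29 and NAALAD2 −1.06 ± 0.30 (0 of 8 higher for each), on 1 to 84 and 1 to 159 counts per library. EdgeR called 0 of 13043 genes. At an unadjusted p under 0.05 there were 397 genes (189 higher and 208 lower), against 652 expected by chance, and 55 genes moved the same way in all 8 lines against 101.9 by chance (0.781%). DESeq2 called 0. Limma-voom called 3, named here after their values were seen: GPNMB at 1.27 (adjusted p = 0.0445) and TIMP3 at 1.68 (0.0246) higher and WNT10A at −0.88 (0.0445) lower. TIMP3, an inhibitor of metalloproteinases, was abundant in THP1 (11891 to 44630 counts), with 1 to 68 counts in each other library. With no expression filter edgeR called VCAN higher and RN5-8S1 and AGT lower.

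In the 4 MLL-fusion lines the question was whether the peptide changed genes in leukemias driven by a fusion of MLL, whose unfused protein belongs to a complex with DPY30. The interferon response was higher with Y518R, with 23 of 24 members above 0 and a median log2 change of 0.34, and the ATF4 and amino acid response was lower, with 0 of 25 above 0 and a median of −0.15. Both values came mainly from THP1. S phase genes were higher in all 26 members (median 0.14), and 28 of 30 MYC targets (0.10) and 12 of 15 B cell markers (0.11) lay above 0. Camera called these 5 of 25 lists at the preset correlation (adjusted p = 1.34e-08 for S phase, 1.22e-05 for ATF4, 3.93e-05 for MYC targets, 4.92e-05 for interferon and 0.0499 for B cell markers), and adjusted p = 0.809 with an estimated correlation for each. Fry called 0 (lowest adjusted p 0.775). Without THP1 the interferon list was below 0 (adjusted p = 0.621) and the ATF4 list above 0 (0.206); without MOLM13 the MYC target call was lost (0.565). The B cell call was lost without THP1 (0.243), RS4-11 (0.176), KOPN8 (0.253) or RAJI (0.0699), and with no replicate block (0.803). By line, the B cell median over detected members was 0.060 in RS4-11 (10 of 14 above 0) and 0.106 in KOPN8 (13 of 15). In the monocytic lines few members were detected, with −0.711 in MOLM13 (2 of 6) and 0.388 in THP1 (5 of 7).

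Members of these lists, none of which passed over all genes, were MX1 at 0.89 ± 0.29 (SE; 3 of 4 lines higher), OASL at 1.07 ± 0.41 (4 of 4) and ISG15 at 0.48 ± 0.20 (4 of 4), all antiviral genes induced by interferon. In the ATF4 list, the cystine transporter SLC7A11 was at −0.81 ± 0.27 (1 of 4 higher), asparagine synthetase ASNS at −0.30 ± 0.11 (0 of 4) and STC2 at −0.54 ± 0.24 (2 of 4). The ribonucleotide reductase genes RRM2 and RRM1 were at 0.30 ± 0.095 and 0.25 ± 0.086 and the helicase subunit MCM5 at 0.28 ± 0.099, each higher in 4 of 4 lines. ODC1 was at 0.42 ± 0.14 (4 of 4), MRTO4 at 0.24 ± 0.099 (4 of 4) and the small nucleolar ribonucleoprotein gene RRP9 at 0.46 ± 0.20 (3 of 4). The B cell genes POU2AF1 and CD79A were at 0.20 ± 0.12 (3 of 4) and 0.14 ± 0.090 (4 of 4). Adjusted over the list alone, 2 members passed against 0 over all genes: MS4A1, which encodes CD20, at 0.81 ± 0.18 (3 of 4 lines higher; list-alone adjusted p = 0.00701, edgeR) and ME1, a malic enzyme in the NRF2 list (list-alone adjusted p = 0.0287), lower in 4 of 4 lines. MS4A1 was abundant only in KOPN8 among these lines (293 to 637 counts), with 7 to 27 counts per library in the other 3.

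By edgeR 0 genes were called in the MLL-fusion lines (lowest adjusted p 0.574), with 770 genes at an unadjusted p under 0.05 (405 higher and 365 lower; 652 by chance) and 1782 in the same direction in 4 of 4 lines against 1630 by chance (12.5%). The lowest p values belonged to TYMP, thymidine phosphorylase, at 0.72 ± 0.15 (4 of 4 higher), to the corepressor gene TLE2 at 1.84 ± 0.38 (4 of 4 higher, with 0 to 31 counts per library) and to NUP62CL, which went from 0 to 28 counts in THP1, at least 9.76-fold higher, and had 0 counts in the other MLL-fusion libraries. The lowest p among lower genes belonged to the pseudogene HERC2P2 at −0.44 ± 0.078, OSBPL10 at −1.22 ± 0.26 (1 to 44 counts per library) and FLJ45340 at −0.37 ± 0.079, each lower in 4 of 4 lines at adjusted p = 0.574; HERC2P2 and FLJ45340 are uncertain because close copies exist. DESeq2 called HERC2P2 (−0.44, adjusted p = 0.00396). Limma-voom called 18 higher and 2 lower, HERC2P2 among the lower (adjusted p = 0.022) and TYMP among the higher (0.0102), and with no filter edgeR called 40 higher and 12 lower. Leaving out MOLM13 gave 3 calls, the NADPH oxidase gene CYBB at 1.93 and ALOX5 at 1.78 higher and AZU1 at −0.96 lower, and leaving out RS4-11 gave 1, NRP2 at 3.86 (adjusted p = 0.00703); these names were chosen after their values were seen.

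The 4 lines without an MLL fusion served to ask whether the peptide acts outside MLL-fusion leukemia. Lists of the interferon response (5 of 24 members above 0, median −0.25), hypoxia and glycolysis (3 of 24, −0.15), replication-dependent histones (0 of 13, −0.49), MHC class II (0 of 10, −0.28) and cytosolic ribosomal proteins (0 of 30, −0.13) were lower with Y518R. MYC targets (27 of 30, 0.089), S phase genes (22 of 26, 0.048) and the ATF4 response (23 of 25, 0.12) were higher. RAJI carried most of these values, and the RAJI 3R library held 44.7% of reads given to no gene against at most 26.9% elsewhere. Camera called these 8 lists at the preset correlation, with adjusted p = 1.45e-07 for hypoxia, 3.46e-07 for histones, 8.57e-07 for ribosomal proteins, 1.83e-06 for interferon, 3.05e-05 for MHC class II, 9.78e-05 for MYC targets, 0.000716 for ATF4 and 0.00287 for S phase. All were lost with an estimated correlation, with adjusted p = 0.621 with an estimated correlation for ATF4 and 0.545 for each of the others, and fry called 0 (lowest adjusted p 0.656). Without RAJI 2 lists were called, and adjusted p was 0.32 for MYC targets, 0.479 for S phase, 0.32 for interferon, 0.136 for hypoxia, 0.516 for histones and 0.201 for MHC class II; without K562 it was 0.186 for ATF4. With no replicate block the S phase (0.0978) and MHC class II (0.239) calls were lost.

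Among interferon genes, the transcription factor IRF7 was at −0.53 ± 0.20 (SE; 1 of 4 lines higher), IFIT3 at −0.60 ± 0.29 (0 of 4) and IFIT2 at −0.57 ± 0.30 (1 of 4). Among glycolysis and hypoxia genes, the aldolase ALDOC was at −0.41 ± 0.15 (1 of 4), the collagen hydroxylase P4HA1 at −0.24 ± 0.091 (0 of 4) and the enolase ENO2 at −0.66 ± 0.28 (0 of 4). HLA-DQA1, HLA-DRB1 and CIITA, the regulator of MHC class II genes, were at −0.39 ± 0.15, −0.42 ± 0.20 and −0.28 ± 0.15. Histones HIST1H2BD, HIST1H4H and HIST1H2BJ were at −0.52 ± 0.23, −0.92 ± 0.49 and −0.72 ± 0.42, and the ribosomal proteins RPS27A, RPL19 and RPL8 at −0.15 ± 0.099, −0.15 ± 0.10 and −0.16 ± 0.11. On the higher side, UTP20, MRTO4 and NOP56 were at 0.17 ± 0.083, 0.16 ± 0.099 and 0.12 ± 0.071, POLE and CCNE2 at 0.15 ± 0.076 and 0.18 ± 0.10, and SLC7A5, SLC1A5 and CHAC1 at 0.29 ± 0.19, 0.15 ± 0.098 and 0.40 ± 0.28. None passed over all genes; adjusted over the list alone 1 did, the metallothionein MT1G (adjusted p = 0.0326, edgeR), which had 7 counts with 3R and 0 with Y518R in K562, at least 3.05-fold lower, and 0 or 1 count in each other library of this class.

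EdgeR called 0 genes in these lines (lowest adjusted p 1), with 206 at an unadjusted p under 0.05 (54 higher and 152 lower; 652 by chance) and 1198 in the same direction in 4 of 4 lines against 1630 by chance. The lowest p belonged to RGS1, a regulator of G protein signalling, at −1.89 ± 0.44, and to the lymphocyte receptor gene SLAMF1 at −0.96 ± 0.23. RGS1 was measurable in RAJI alone (2015 to 561 counts, against 0 or 1 count in each of the other 6 libraries), and SLAMF1 mainly there (2293 to 889 counts). KCNMB1 at −2.89 ± 0.76 went from 28 to 2 counts in JURKAT and from 7 to 0 in RAJI. Higher genes with the lowest p were the protease TMPRSS9 at 0.92 ± 0.27 (4 of 4 lines), RTP4 at 1.92 ± 0.59 on 0 to 20 counts and HOXA2 at 2.82 ± 0.87 on 0 to 15 counts per library. DESeq2 called 0, limma-voom called RGS1 (−1.83, adjusted p = 0.00095) and SLAMF1 (−1.25, adjusted p = 0.0109), and edgeR with no filter or with at least 10 counts in 2 libraries called RN5-8S1, an RNA without a poly(A) tail.

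The difference between the classes of line was tested directly. The interferon list had the largest gap, with 23 of 24 members more positive in MLL-fusion lines and a median difference of 0.58 on the log2 scale, followed by histones (13 of 13, 0.53), MHC class II (10 of 10, 0.33), B cell markers (13 of 15, 0.24), hypoxia and glycolysis (23 of 24, 0.18), cytosolic ribosomal proteins (30 of 30, 0.16), S phase (22 of 26, 0.097) and cholesterol synthesis (19 of 25, 0.085). The ATF4 response (1 of 25 above 0, −0.26), NRF2 targets (6 of 18, −0.11) and the SET1/MLL complex with its DPY30 partners (5 of 19, −0.035) were more negative. Camera called these 11 lists at the preset correlation. In the order given, the adjusted p was 1.63e-09, 0.00269, 1.64e-05, 0.0142, 1.12e-05, 1.64e-05, 0.0181 and 0.0312 for the higher lists, and 1.28e-08, 0.00962 and 0.0375 for the lower ones. With an estimated correlation the adjusted p was 0.527 for interferon, MHC class II, B cell markers, hypoxia, NRF2 and the SET1/MLL complex, 0.551 for ATF4, 0.623 for histones and cholesterol, and 0.662 for ribosomal proteins and S phase; fry called 0 (lowest adjusted p 0.579).

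Most of these calls, 9 of 11, were lost when 1 line was left out. Without THP1 the adjusted p was 0.135 for ATF4, 0.614 for NRF2, 0.0511 for S phase, 0.0708 for cholesterol and 0.0708 for B cell markers, and without RAJI it was 0.0537 for hypoxia, 0.633 for histones, 0.0666 for NRF2, 0.143 for the SET1/MLL complex, 0.0676 for cholesterol and 0.174 for B cell markers. Without MOLM13 it was 0.147 for ribosomal proteins, 0.458 for S phase and 0.116 for the SET1/MLL complex. The cholesterol call was also lost without KOPN8 (0.0978), K562 (0.0564) or JURKAT (0.354), the S phase call without JURKAT (0.101) or P493-6 (0.116), the SET1/MLL call without RS4-11 (0.0796), K562 (0.0874) or P493-6 (0.0581), and the B cell call without RS4-11 (0.055), KOPN8 (0.0885) or JURKAT (0.0733). The interferon and MHC class II calls held with any 1 line left out, at adjusted p of at most 0.00581 and 0.0397, and were lost without RAJI and THP1 together (0.736 and 0.144); 7 lists were then called. MHC class II medians in the other lines could be taken only in RAJI (−0.507) and P493-6 (−0.0698). In K562 and JURKAT fewer than 5 members were at a CPM of 1 or more. With no replicate block 5 lists were called.

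Members with the lowest p in these lists, none passing over all genes, were IRF7 at 0.78 ± 0.27 (SE of the difference) and ISG15 at 0.78 ± 0.27 for interferon, and ASNS at −0.45 ± 0.16, SLC7A11 at −0.97 ± 0.37 and CHAC1 at −1.0 ± 0.40 for ATF4. NRF2 members ME1 and GCLM were at −0.55 ± 0.24 and −0.39 ± 0.17. HLA-DRA, HLA-DPA1 and CD74 were at 0.54 ± 0.19, 0.61 ± 0.26 and 0.32 ± 0.15. EGLN3, P4HA1 and PGK1 of the hypoxia list were at 1.55 ± 0.54, 0.31 ± 0.13 and 0.25 ± 0.11, and the ribosomal proteins RPL8 and RPL10A at 0.32 ± 0.16 and 0.29 ± 0.15. Histones HIST1H1C, HIST1H4H and HIST1H2BD were at 0.54 ± 0.29, 1.19 ± 0.73 and 0.53 ± 0.34. The replication genes GINS2, RRM2 and RRM1 were at 0.25 ± 0.13, 0.25 ± 0.13 and 0.22 ± 0.12, and the sterol genes TMEM97, FDPS and FDFT1 at 0.37 ± 0.14, 0.23 ± 0.12 and 0.23 ± 0.12. Of the SET1/MLL complex, the methyltransferase gene SETD1B was at −0.37 ± 0.13 and the methyltransferase gene listed as MLL4 at −0.17 ± 0.10, while ASH2L was at 0.20 ± 0.13. VPREB1 and IGLL1, parts of the pre-B cell receptor, were at 0.68 ± 0.26 and 0.47 ± 0.26. Adjusted over the list alone 2 members passed, MS4A1 (adjusted p = 0.00684) and MT1G (0.0329), against 0 over all genes.

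EdgeR called 0 genes for the difference (lowest adjusted p 0.416), with 495 at an unadjusted p under 0.05 (279 higher and 216 lower; 652 by chance). RGS1 had the lowest p, at 3.13 ± 0.52 (adjusted p = 0.416): it was higher with Y518R in 4 of 4 MLL-fusion lines, from 95 to 133 counts in MOLM13, 12 to 86 in THP1, 162 to 243 in RS4-11 and 25 to 68 in KOPN8, and lower in RAJI. TLE2 was at 2.22 ± 0.43 (adjusted p = 0.603), the interferon-inducible gene EPSTI1 at 2.28 ± 0.49 (0.991) and MS4A1 at 1.0 ± 0.22 (0.991), and NUP62CL was also among the 5 with the lowest p (0.603). More negative in MLL-fusion lines were HERC2P2 at −0.55 ± 0.11 (adjusted p = 0.603), the translation regulator GIGYF1 at −0.45 ± 0.11, TMPRSS9 at −1.43 ± 0.36, OSBPL10 at −1.15 ± 0.30 and the tropomyosin gene TPM2 at −0.91 ± 0.24 (adjusted p = 1 for these 4). In opposite directions in every line of the 2 classes were 104 genes, against 101.9 by chance. DESeq2 called RGS1 (3.23, adjusted p = 0.0046) and HERC2P2 (−0.55, adjusted p = 0.0411), limma-voom called RGS1 (2.96, adjusted p = 0.00176) and CYBB (1.81, adjusted p = 0.0273), and edgeR with no filter called 8 higher and 1 lower. Leaving out THP1 gave a call of RGS1 (2.77, adjusted p = 0.00552), and leaving out MOLM13 a call of CYBB (2.09, adjusted p = 0.026).

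Whether the lines responded alike was asked of all genes together. The mean correlation of log2 ratios over the 28 pairs of lines, across genes, was 0.000161, and pairs ran from −0.068 to 0.11 by Pearson and from −0.195 (K562 and JURKAT) to 0.228 (MOLM13 and KOPN8) by Spearman. The exact 2-sided sign-flip test over the 8 lines gave p = 0.984. The mean was 0.029 within the MLL-fusion lines, −0.0039 within the other lines and −0.0089 between the classes. Genes are not independent replicates, and the test treats lines as the replicates.

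**Figure D2:**
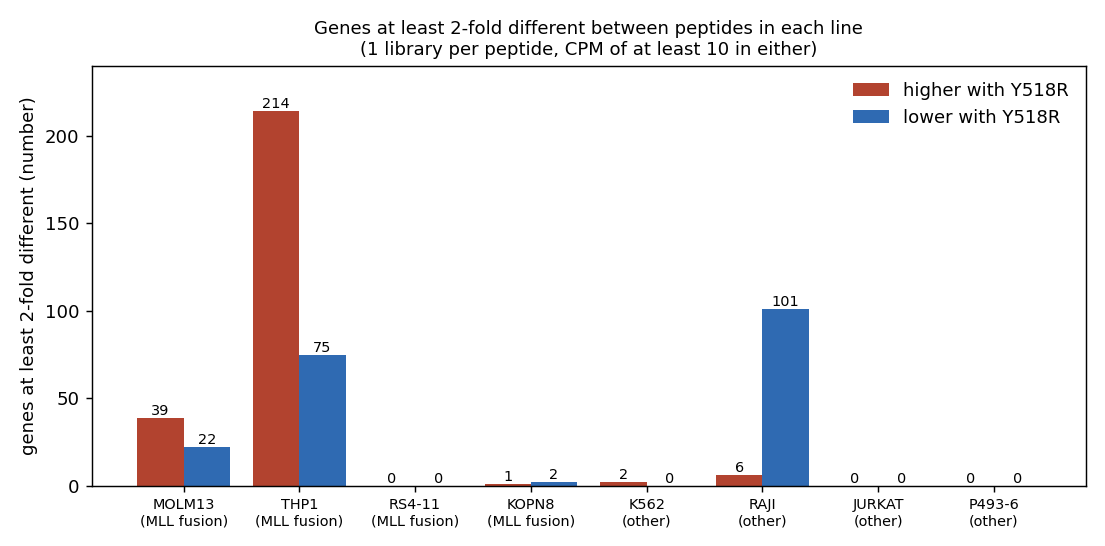
Number of genes at least 2-fold higher or lower with Y518R than with 3R (y axis) in each cell line (x axis), among genes at 10 CPM or more in either library, with no replicate within a line. THP1 has 214 higher and 75 lower, RAJI 6 higher and 101 lower, MOLM13 39 higher and 22 lower, and each of the other 5 lines at most 3 in all.

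Single lines are described without a test, since each had 1 library per peptide. Random lists ignore that genes of a list move together, so a median beyond all of them is a description only. Genes at least 2-fold different numbered 289 in THP1 (2.95% of genes at 10 CPM or more), 107 in RAJI, 61 in MOLM13, 3 in KOPN8, 2 in K562 and 0 in RS4-11, JURKAT and P493-6. In MOLM13 the balance of 39 higher and 22 lower turned over with library size alone (23 higher and 33 lower) and at a CPM of 1 or more (186 higher and 293 lower). The SD of log2 ratios was 0.41 in THP1, 0.36 in RAJI, 0.33 in MOLM13 and 0.15 to 0.18 in the other 5 lines. List members and marker genes named for single lines were chosen after their values were seen, unless said to be a line's most extreme.

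**Figure D3:**
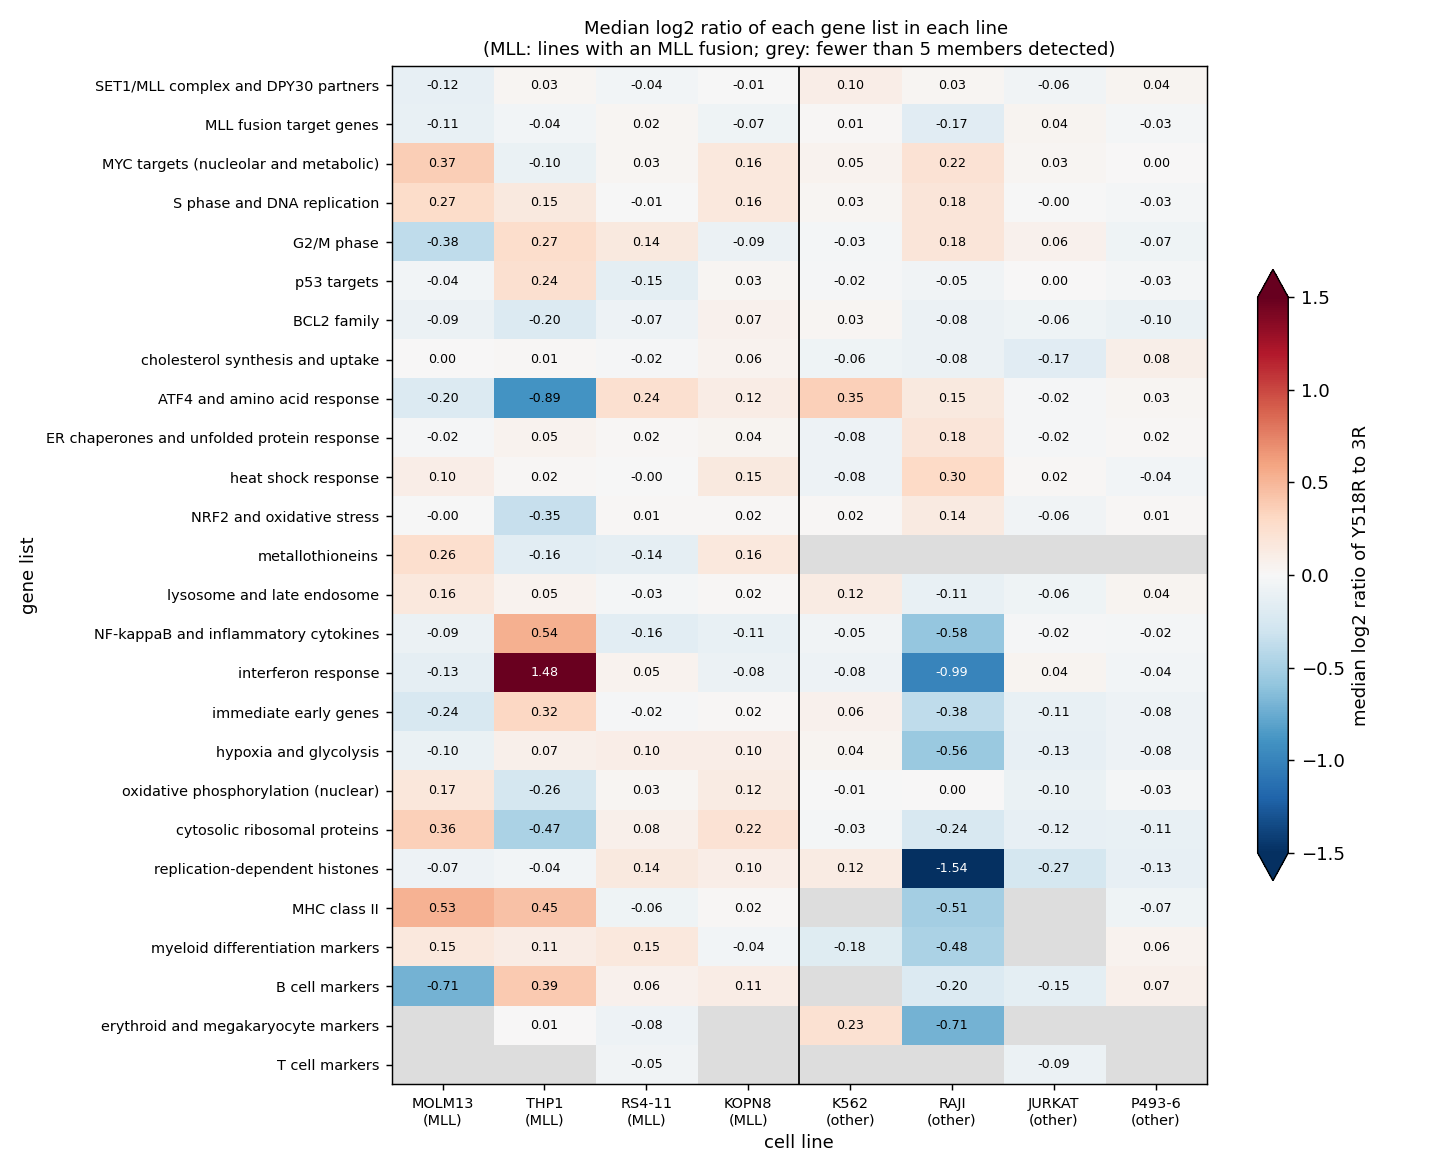
Median log2 ratio of Y518R to 3R (color) of each gene list (vertical axis) in each of the 8 cell lines (horizontal axis), with no replicate within a line. The interferon list is at 1.48 in THP1 and −0.99 in RAJI, and the histone list at −1.54 in RAJI.

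In THP1, a monocytic line, the interferon response was higher with Y518R in all 26 detected members (median 1.48, 19 of them at least 2-fold). MX1 went from 2778 to 11475 counts (log2 ratio 2.11), OASL from 141 to 590 and ISG15 from 1227 to 3216. The ATF4 and amino acid response was lower in all 26 members (median −0.89, 11 at least 2-fold lower), with SLC7A11 from 3973 to 930 counts (−2.03) and CHAC1, a glutathione-degrading enzyme, from 2131 to 524 (−1.96). The median of interferon genes lay above, and that of ATF4 genes below, all 10000 random lists. The myeloid list was mixed (median 0.11, 12 of 22 above 0). Its members at least 2-fold lower were the granule protein genes CTSG (95601 to 19190 counts, −2.25), PRTN3 (43851 to 13156, −1.67), MPO (437 to 175, −1.25) and AZU1 (79385 to 37886), and those at least 2-fold higher were VCAN (852 to 10525, 3.69), ITGAM (351 to 1734, 2.36), CD14 (137 to 536, 2.01) and FCER1G (4365 to 10058, 1.27); LYZ went from 23955 to 15997 counts. NF-kappaB targets had a median of 0.54, with 17 of 18 above 0 and TNF from 792 to 2068 counts, and immediate early genes had a median of 0.32 with 24 of 28 above 0. Ribosomal proteins (median −0.47, 0 of 30 above 0), oxidative phosphorylation genes (−0.26, 0 of 28) and NRF2 targets (−0.35, 3 of 18) were lower, and G2/M genes (0.27, 21 of 27) and p53 targets (0.24, 14 of 20) higher. The most extreme genes were the neuropilin gene NRP2 (18 to 509 counts, log2 ratio 4.72, counting interval 4.21 to 5.65) and the lysophospholipase gene ENPP2 (59 to 1071, 4.2, 3.87 to 4.65) upward, and USH1C (484 to 26, −4.05, −4.78 to −3.59) and ORM1 (240 to 26, −3.04, −3.79 to −2.56) downward; ORM1 has a close paralog.

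In MOLM13, also a monocytic line with MLL-AF9, both growth-related lists and the ATF4 response differed. MYC targets had a median of 0.37 (29 of 30 above 0) and ribosomal proteins of 0.36 (30 of 30), both above all 10000 random lists, beside a log2 ratio of 0.94 for MYC itself. RRP9 went from 491 to 1255 counts (1.52) and ODC1 from 1740 to 3433 (1.15). S phase genes had a median of 0.27 (23 of 26), while G2/M genes had −0.38 (2 of 27 above 0), with PLK1 from 2466 to 1551 counts and CENPF from 5101 to 3170. The ATF4 list had a median of −0.20 (4 of 26 above 0), and its median and that of G2/M genes lay below all 10000 random lists. Immediate early genes had a median of −0.24 (6 of 28 above 0), above 0.12% of random lists, and the interferon list had −0.13 (9 of 22). MPO went from 567 to 197 counts. The most extreme genes were SAMD4A (218 to 38 counts, −2.31, −2.89 to −1.85) and GNRH1 (199 to 55, −1.66, −2.14 to −1.25) downward, and CRIP2 (88 to 240, 1.60, 1.26 to 1.99) and SULT1A1 (76 to 207, 1.60, 1.23 to 2.01) upward; SULT1A1 is uncertain because of near-identical copies.

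In RAJI nearly all genes past 2-fold were lower with Y518R, 101 of 107. RNAs without poly(A) tails led: RN5-8S1, a 5.8S ribosomal RNA, went from 2189 counts to 0, at least 736-fold lower, RPPH1, the RNA of RNase P, from 4008 to 35 (log2 ratio −6.80, counting interval −7.37 to −6.37) and RMRP from 3458 to 40. In the 3R library 44.7% of reads fell in no gene (16061749 reads) against 23.4% with Y518R (6073903 reads). Summed histone genes and RNA genes taken to lack poly(A) tails were at 1772 CPM in RAJI 3R and 677 in RAJI Y518R. Both K562 libraries were higher (3079 and 3280), but HIST1H1C alone was at 855 and 929 CPM there. RPPH1 and RMRP were at 0.302 and 1.21 CPM in K562 3R and 2.93 and 3.92 in K562 Y518R, against 209 and 181 in RAJI 3R. Replication-dependent histones in RAJI had a median of −1.54 (0 of 12 above 0, 10 at least 2-fold lower), with HIST1H1E from 369 to 5 counts. Polyadenylated transcripts were lower too: interferon genes had a median of −0.99 (1 of 19 above 0; IFI44L from 451 to 23 counts, −4.23), hypoxia and glycolysis genes −0.56 (1 of 23; ENO2 from 284 to 55), NF-kappaB targets −0.58 (0 of 16; TNFAIP3 from 7266 to 3197) and MHC class II genes −0.51 (0 of 10; CIITA from 5909 to 4066). The medians of the interferon, hypoxia, NF-kappaB, histone, MHC class II and ribosomal protein (−0.24) lists lay below all 10000 random lists. Heat shock genes (0.30, 15 of 16), MYC targets (0.22, 28 of 30), S phase (0.18, 23 of 26) and G2/M genes (0.18, 23 of 27) were higher. The most extreme higher genes were DPF1 (85 to 217 counts, 1.33, 0.97 to 1.72) and FAM98C (103 to 240, 1.20, 0.87 to 1.56).

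**Figure D4:**
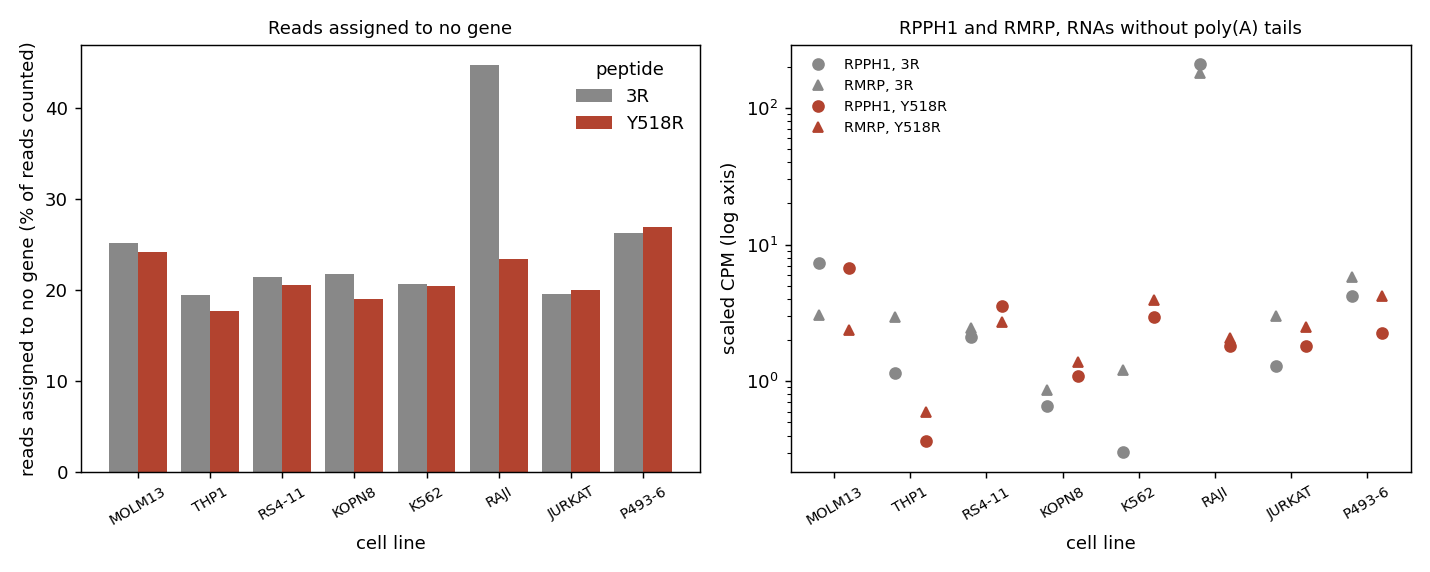
The RAJI 3R library beside the 15 others, in the percent of reads given to no gene and in the scaled CPM (log axis) of RPPH1 and RMRP, RNAs without poly(A) tails. RAJI 3R has 44.7% of reads in no gene, against 17.7% to 26.9% in the others. RPPH1 and RMRP are at 209 and 181 CPM in RAJI 3R, against 1.81 and 2.07 in RAJI Y518R. In K562 they are at 0.302 and 1.21 CPM with 3R and 2.93 and 3.92 with Y518R.

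The remaining 5 lines differed little between peptides. In K562 the ATF4 response was higher (median 0.35, 23 of 25 above 0; CHAC1 from 668 to 1704 counts and SESN2 from 1953 to 4459), and so were erythroid markers (0.23, 12 of 16; HBZ from 5198 to 9184 counts), both above all random lists; the genes at least 2-fold different were JDP2 and the globin HBD, both higher. In RS4-11 the ATF4 list had a median of 0.24 (24 of 25 above 0), G2/M genes 0.14 (25 of 27) and p53 targets −0.15 (3 of 21). In KOPN8 ribosomal proteins had 0.22 (29 of 30), S phase genes 0.16 (22 of 26) and MYC targets 0.16 (27 of 30); CYP1A1, a target of the aryl hydrocarbon receptor, went from 543 to 213 counts (−1.68), and the other genes past 2-fold were SGK494, lower, and C7orf55, higher. In JURKAT cholesterol synthesis genes had −0.17 (3 of 25 above 0), with the lanosterol synthase gene LSS from 464 to 360 CPM (−0.37), and ribosomal proteins −0.12 (3 of 30); the T cell markers had −0.092 (3 of 15 above 0, above 2.2% of random lists). In P493-6 cholesterol genes had 0.084 (22 of 25 above 0) and ribosomal proteins −0.11 (1 of 30).

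The most extreme genes of these lines had few counts, though by the rule each had at least 200 over both libraries. They were ATP1B1 (−1.27) and APOE (−1.22) downward and PSD2 (1.17) and PPAPDC2 (1.14) upward in RS4-11, and CYP1A1 and NOXA1 (−1.44) downward and RSG1 (1.30) and SMPD3 (1.19) upward in KOPN8. In K562 they were AMZ2P1 (−1.37) and SFT2D2 (−1.21), and FBXL8 (1.14) and TXNDC5 (1.14). In JURKAT they were SH3RF3 (−1.39) and LOC641298 (−1.19), and MST1P2 (1.0) and PROS1 (0.98). In P493-6 they were the microRNA precursor MIR3648 (−2.48), from 224 to 40 counts, and ANKRD9 (−1.46), and AGAP4 (1.23) upward. Other RNA genes without poly(A) tails were also lower there with Y518R, RN5-8S1 from 115 to 0 counts and MIR3687 from 76 to 36, and MIR3648 went from 2978 to 155 counts in RAJI. AMZ2P1, TXNDC5, MST1P2, LOC641298 and AGAP4 are uncertain because they share sequence with copies or overlap other genes.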

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

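Chosen only after seeing the result, the tests in this part are the RAJI interferon and S phase medians, the MOLM13 medians set beside THP1, the sign-flip tests of lists and the swapped-label counts of genes. A value was set apart when its gap to the next value, as a share of the whole range, passed Dixon's 95% limit. Of 61 groups of values looked at, 11 held such a value. Chance alone would set a value apart in about 1 of 20 groups if values were normally distributed and groups independent. These groups reuse the same pairs of libraries, and CTTN and NUP62CL were chosen by their low p. The 11 therefore cannot be read as an excess over chance. The other results here are lists that differed between classes of line by camera at its preset correlation.

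The RAJI 3R library was apart in reads given to no gene (44.7%, next 26.3% among 3R libraries), and RAJI was apart in the medians of replication-dependent histones (−1.54, next −0.27) and hypoxia genes (−0.56, next −0.13). Polyadenylated histone variants had a median of 0.114 in RAJI over 7 genes, of which H3F3A had 0 counts and H1F0 had 7 and 4, and the other 5 lay between 0.035 (H1FX) and 0.305 (H2AFV), which is consistent with carry-over of RNA without poly(A) tails into the 3R library as the source of the histone and RPPH1 values. Some listed histone genes may also give mRNAs with tails, which was not tested. Carry-over of this kind does not account for the interferon median of −0.988, since those transcripts are polyadenylated. Olfactory receptor genes had −27 counts in 3R relative to Y518R, which argues against genomic DNA, and the S phase median of 0.178 argues against fewer RAJI cells in S phase with Y518R. Whether the interferon and hypoxia values come from the peptide or from other differences between these 2 libraries stays open.

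THP1 was apart in genes at least 2-fold different (289, next 107) and in the medians of the interferon (1.48, next 0.052), ATF4 (−0.894, next −0.20), NRF2 (−0.347, next −0.059) and p53 target lists (0.241, next 0.027). Admixture of another line of the series into the THP1 Y518R library was argued against by a highest median share of 0.00403, for MOLM13 over 19 genes. Admixture into the THP1 control library was not tested. A response shared by the MLL-AF9 lines was argued against for interferon by the MOLM13 median of −0.129. For ATF4 the MOLM13 median of −0.202 argues against a shared response of the THP1 size, and a smaller shared response stays open. That this median lay below all 10000 random lists does not decide it. Members of random lists were drawn independently, while ATF4 genes move together (estimated correlation 0.787 over 8 lines). With 1 library per peptide, an effect of the peptide on THP1 cannot be told from a difference between cultures.

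The S phase and MYC target lists were called over 8 lines at the preset correlation and lost with an estimated one (adjusted p = 0.602 and 0.712). Exact sign-flip tests over lines gave p = 0.0547 for S phase and p = 0.141 for MYC targets, both above 0.05. With 8 lines these values cannot tell genes of a list moving together within single lines from a small rise in several lines. With peptide labels swapped within lines, 98 of 100 labelings called as many lists as the real one (3 real, at most 17 elsewhere), so chance cannot be excluded for the number of lists called. A small rise of replication genes in most lines stays open at this number of lines. No biological explanation was tested.

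For lists that differed between classes 15 of 35 splits called as many as the real 11, and at most 17, so chance cannot be excluded there either. Counts of genes decide nothing, because the real count was 0 and any split calls at least as many: 100 of 100 over 8 lines (at most 0 elsewhere) and 35 of 35 for the difference (at most 2 elsewhere). In the MLL-fusion lines there were too few labelings (8) for a share under 0.05: genes 0 real and at most 0 elsewhere (8 of 8 as many), lists 5 real and at most 12 elsewhere (7 of 8). The other lines had too few as well: genes 0 real and at most 1 elsewhere (8 of 8), lists 8 real and at most 13 elsewhere (7 of 8).

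K562 Y518R was apart in the summed CPM of histone genes and RNA genes taken to lack poly(A) tails (3280, next 742 among Y518R libraries), and K562 3R had 3079. The histone HIST1H1C alone was at 929 CPM in K562 Y518R and 855 in K562 3R. RPPH1 and RMRP were at only 2.93 and 3.92 CPM in K562 Y518R. CTTN was apart in THP1 (log2 ratio 1.60, next 0.45). NUP62CL was apart in THP1 among the MLL-fusion lines (3.83 with the prior count, from 0 to 28 counts, next 0).

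Lists that differed between classes had median differences of −0.035 for the SET1/MLL complex and DPY30 partners, 0.0972 for S phase, 0.085 for cholesterol synthesis, −0.262 for ATF4, −0.108 for NRF2, 0.575 for interferon, 0.183 for hypoxia, 0.16 for ribosomal proteins, 0.531 for replication-dependent histones, 0.328 for MHC class II and 0.235 for B cell markers. All 11 were lost with an estimated correlation. For histones, the RAJI value described above sets the difference, as the adjusted p without RAJI was 0.633.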

How the results depend on the processing

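Leaving out RAJI and THP1 together and the sign-flip test of lists were chosen only after seeing the result. The 0 genes called by edgeR held under RLE and upper quartile scaling, a minimum count of 50, robust estimation, an adjusted p of 0.10, separate class fits and the GC and length correction. Over 8 lines limma-voom called 2 higher and 1 lower, no filter 1 higher and 2 lower, and at least 10 counts in 2 libraries 1 lower. In MLL-fusion lines limma-voom called 18 higher and 2 lower, no filter 40 and 12, DESeq2 1 lower, and leaving out a line 0 to 2 higher and 0 to 1 lower. In the other lines limma-voom called 2 lower, no filter 1 lower and at least 10 counts in 2 libraries 1 lower. For the difference DESeq2 called 1 higher and 1 lower, limma-voom 2 higher, no filter 8 higher and 1 lower, and leaving out a line 0 to 1 higher. The 3 lists called over 8 lines became 8 with limma-voom, 5 without RAJI and THP1, 3 to 11 with a line left out, and 0 with an estimated correlation, with fry and with the sign-flip test. The 5 in MLL-fusion lines became 0 with an estimated correlation and 0 with fry. The 8 in the other lines became 16 with limma-voom, 4 without RAJI and THP1, 2 to 15 with a line left out, and 0 with an estimated correlation and 0 with fry. The 11 that differed between classes became 7 without RAJI and THP1, and 0 with an estimated correlation and 0 with fry. With no replicate block, thus without the pairing by cell line, 5 lists differed between classes and 0 genes were called in any comparison. With limma-voom the histone calls were lost over 8 lines (adjusted p = 0.478), in the other lines (0.0615) and for the difference (0.231), and so was the SET1/MLL difference (0.0515). In MLL-fusion lines the adjusted p of the ATF4 list was 0.211 without RAJI and THP1 and 3.15e-14 to 0.206 with a line left out, and that of the interferon list 0.545 and 1.72e-07 to 0.621, both turning direction without THP1. The mean correlation between lines was −0.0037 by Spearman, −0.0167 for genes at a mean log2 CPM of 5 or more, −0.0014 with a prior count of 10 and −0.00626 to 0.00551 with a line left out. Genes at least 2-fold different depended on the lowest CPM allowed: at a CPM of 1 or more there were 479 in MOLM13, 856 in THP1, 153 in RS4-11, 223 in KOPN8, 221 in K562, 566 in RAJI, 152 in JURKAT and 197 in P493-6, and at 50 or more 14 in MOLM13, 112 in THP1, 0 in KOPN8, 0 in K562 and 30 in RAJI. In MOLM13 the balance turned from 39 higher and 22 lower to 23 higher and 33 lower with library size alone and 186 higher and 293 lower at a CPM of 1 or more. With library size alone there was 1 in K562 and 1 in JURKAT, and with a prior count of 10 there was 1 in K562. With a line left out the mean log2 ratio ran from −0.0105 to 0.0894 for ASH2L, −0.0975 to 0.134 for MYC, −0.429 to −0.0131 for MEIS1, −0.131 to 0.216 for BCL2, −0.0296 to 0.119 for CDKN1A and −0.01 to 0.124 for MKI67, and DPY30 and HOXA9 kept their sign. For HOXA9 these means take in lines with 0 or 1 count in each library. The cause was not tested for any of these. Depth limits genes near the floor, as a count of 0 allows up to 0.155 CPM of the library total.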

Other observations

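Chosen only after seeing the result, the test in this part is the relation of list medians to the MYC ratio across lines. MPO, a marker of granulocyte precursors, was lower with Y518R in both MLL-AF9 lines, from 567 to 197 counts in MOLM13 and from 437 to 175 in THP1. Of these lines only THP1 had lower CTSG and PRTN3: in MOLM13 CTSG went from 15419 to 16562 counts and PRTN3 from 3260 to 3509. TNF was higher in THP1 and went from 3169 to 1941 counts in MOLM13.

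Lines with a higher MYC ratio were asked to have a higher median of MYC targets, since MYC drives nucleolar and ribosomal genes. Over the 8 lines the Pearson r was 0.934 (exact permutation p = 0.000372, adjusted 0.000744 over the 2 relations computed) and Spearman's rho 0.929 (exact p = 0.00223, adjusted 0.00446), and r was 0.765 without MOLM13 and THP1. For ribosomal proteins r was 0.863 (exact p = 0.00895, adjusted 0.00895) and rho 0.786 (exact p = 0.0279, adjusted 0.0279), and r fell to 0.383 without those lines, on which this relation rests. Both values are in line with MYC mRNA and its targets varying together between libraries; they do not tell whether the peptide set the MYC ratio.

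Olfactory receptor genes had 4431 counts in K562 3R and 6038 in K562 Y518R, against 220 and 247 in RAJI.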
